A study of Mus musculus with 7 samples.

How the data were processed

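Total RNA of isolated labial cervical loops was extracted with a column kit and made into biotinylated cRNA with a Nugen kit for Illumina arrays, per the labels' protocols. Each of the 3 control and 4 mutant samples gave 1 array. The chip of each array was read from the array identifiers in the labels, and the 2 chips held 4 and 3 arrays.

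The probe intensity values were deposited without normalization, per the file headers, as the mean brightness of the beads of each of 25697 probes. The deposited table gives beside each intensity a detection p-value against the negative control beads of the same array, per the file headers, and the number of beads averaged, another deposited value. The software that summarised the beads is not given in the sources used here. The authors also deposited log2 values, normalised between arrays and adjusted with ComBat for the array ID with the sample type as covariate, as the name of the deposited table says. The same log2 values make up the series matrix, with column medians of 6.61. How the arrays were normalised before ComBat, and whether a background was subtracted, is not given in the sources used here. The comparison made by the authors lists a p-value and a q-value per probe, and a fold score that was found, from the deposited group means, to be a signed ratio of mean log2 values. Its detection count runs up to 16 arrays, more than the 7 arrays used here.

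From the deposited intensities, the background was corrected with limma 3.58.1 in R 4.3.3 by normal-exponential convolution, with the negative controls inferred from the detection p-values and an offset of 16. The values were then quantile normalised between arrays and taken to log2. A log2 difference of a dim probe is compressed by the offset. Probes with a detection p-value under 0.05 on at least 3 arrays were tested, 14666 in all, of 10484 gene symbols. Each probe was fitted with limma's lmFit and eBayes on all 7 arrays, with genotype and chip as terms, which left 4 residual degrees of freedom beside 15.5 of the prior. Differences are mutant minus control with the chip as a term, group means and SDs are of the normalised log2 values without it, and p-values are two-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Differences within a chip came from fits to its arrays alone.

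Symbols are those of the array's design, and 8292 of the tested symbols are the same in the RefSeq table of GRCm38.p6, 1781 matched it through an older symbol or a gene ID, and 411 did not match. The array data name no genome build, so the table served only for names and for which genes are neighbours, and no coordinates are given.

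Before the data were examined, 34 gene lists, the design, the alternatives and the rule for naming genes were fixed. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe per gene, the one of highest mean, and adjusted over the 31 lists with at least 5 tested members. Camera with an estimated correlation and fry stand beside it. The array carries lysozyme under 3 symbols that the macrophage list joins as 1 gene. After the data were examined, the brightest of them, Lyz, was taken as the member, so the called Lyzs probe is not in that list. The text names the targeted genes, the called genes with the largest differences (up to 15 in each direction, filled up to 8 by the smallest unadjusted p with values that did not pass), up to 4 called members of each list or otherwise up to 2 of smallest p, and a fixed set of Rheb, Ctgf, Cyr61, Ankrd1, Lats2, Amotl2, Tead1, Itga3, Itga6, Ptk2, Sox2, Krt14, Ccnd1, Cdkn1a, Mki67, Shh, Ambn, Amelx and Sfrp5. A gene chosen after its value was seen is named as such. Other probes of a named gene are given where they bear on it.

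For a gene detected in 1 genotype only, the mean of the bright group was set against the mean, per array of the other group, of the higher of its own value and the lowest value among detected probes. The detection filter, the background correction and its offset, the normalization, the chip term, array weights, the trend and robust options of eBayes, the series matrix values, the threshold, the probe rule of the lists, the replicate number as a block and leaving out each array in turn were tried as alternatives. Without control replicate 3 the second chip holds no control, so the differences are then those of the first chip alone. ComBat was rewritten in R as an alternative, with empirical priors and the genotype as covariate.

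The fit was tested on simulated data, in 10 runs of 14666 probes with the fitted means and spreads of these arrays and 200 probes changed. It recovered 73.9% of changes of 0.5 on the log2 scale, 100% of changes of 1 and 100% of changes of 2, with 13.2 false calls among 196 calls per run on average. A list shifted by 0.13 was called in 10 of 10 simulated runs, with 0 false list calls. The simulation draws independent genes, which real lists are not. With 200 probes changed, many calls also ease the adjusted threshold, so these recovery rates do not carry over to the real arrays with 9 calls. There Bbc3, for example, differed by 0.52 and did not pass (limma adjusted p = 0.163).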

Results

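Gene expression was measured in the labial cervical loop of the mouse incisor, the pocket of epithelium at the base of the tooth that holds the stem cells of the continuously growing enamel organ. Control mice carried floxed alleles of Yap and Taz. Mutant mice carried K14CreER as well, a Cre recombinase that is driven by the keratin 14 promoter and becomes active after tamoxifen. No control carried the Cre, so for every difference below, the Cre itself and the loss of Yap and Taz cannot be told apart. The targeted genes, Yap1 and Wwtr1 (the gene of the TAZ protein), encode transcriptional co-activators that the Hippo pathway holds back. Both genotypes were given 5 mg of tamoxifen on 2 consecutive days at 8 weeks of age, and the loops were taken 48 hours later. Total RNA of 3 control and 4 mutant samples was hybridised to 7 Illumina arrays. The first of 2 BeadChips held 2 control and 2 mutant arrays, and the second held 1 control and 2 mutant arrays. Between 13767 and 14752 of the 25697 probes were detected per array, at a median intensity of 80.8 to 86.2 and a median of 31 to 38 beads per probe. Across the 14666 probes tested, which are not independent of each other, arrays of the same genotype correlated at 0.977 to 0.985 and arrays of different genotypes at 0.978 to 0.986. The number of arrays limits the precision. Because nothing in the labels says that the samples came from separate animals, p-values measure only the spread between these samples.

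The first comparison asked whether the 2 targeted transcripts were lower in the mutant tissue. Yap1 fell by 0.68 on the log2 scale (SE 0.12, limma adjusted p = 0.0443), from a normalised log2 intensity of 7.27 ± 0.10 (SD, n = 3) in control to 6.64 ± 0.25 (SD, n = 4) in mutant arrays, and all 4 mutant arrays lay below the 3 control arrays. The Yap1 difference was -0.74 on the first chip and -0.58 on the second. Wwtr1 measured 4.75 ± 0.20 (SD, n = 3) in control and 4.61 ± 0.26 (SD, n = 4) in mutant arrays. Its log2 difference of -0.15 (95% interval -0.44 to 0.14, adjusted p = 0.819) did not pass the test, and its level lay close to the median of 4.52 over all probes. Each gene had 1 tested probe. The sources used here give neither the floxed exons nor the position of the probes, and a probe outside the deleted exons need not show the deletion. Any mesenchyme in the dissected tissue would lack an active keratin 14 promoter. Yap1 kept its call without mutant replicate 4 (adjusted p = 0.0493) and lost it when any other array was left out (adjusted p = 0.0844 without control replicate 1, 0.163 without control replicate 2, 0.159 without control replicate 3, 0.176 without mutant replicate 1, 0.216 without mutant replicate 2 and 0.122 without mutant replicate 3). It also lost its call without the chip term (adjusted p = 0.125), with median scaling (0.0764), without background correction (0.196) and with the larger offset (0.193). The call was further lost without the detection filter (0.421), in the series matrix values (0.122) and within the first chip alone (0.239). The series matrix values, already adjusted for the array ID, were fitted here with a chip term again. On the same values the authors' deposited table gives Yap1 a q-value of 0.00616.

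The comparison of the genotypes over all probes asked which transcripts differed within days of the tamoxifen course. Of 14666 probes, 9 changed, each of a different gene, with 5 higher and 4 lower in the mutant arrays at adjusted p-values of 0.0443 to 0.0455. Lyzs, the older symbol of Lyz2, which encodes the lysozyme of myeloid cells, rose by 0.74 on the log2 scale (SE 0.12). Cyfip2, a subunit of the actin-regulating WAVE complex, rose by 0.74 (SE 0.12), Ank2, the membrane adaptor ankyrin B, by 0.77 (SE 0.13), and Krt73, a keratin of the inner root sheath of hair, by 0.67 (SE 0.12). LOC546015, listed as the pseudogene Gm5905 in the GRCm38.p6 annotation, rose by 0.91 (SE 0.16) on the called probe, while a second probe of it differed by -0.03 (SE 0.12). Cftr, the chloride channel of secretory epithelia and enamel-forming ameloblasts, fell by 0.97 (SE 0.18). Pdgfc, a platelet-derived growth factor, fell by 0.63 (SE 0.11), and 1110032E23Rik, now named Gask1b, fell by 0.66 (SE 0.12). Lyzs measured 4.62 ± 0.08 (SD, n = 3) in control and 5.38 ± 0.18 (SD, n = 4) in mutant arrays, and Cftr 5.66 ± 0.52 (SD, n = 3) and 4.71 ± 0.24 (SD, n = 4). On the first and the second chip the differences were 0.74 and 0.74 for Lyzs, 0.87 and 0.54 for Cyfip2, 0.92 and 0.55 for Ank2, 0.71 and 0.60 for Krt73, 0.91 and 0.90 for LOC546015, -1.04 and -0.88 for Cftr, -0.61 and -0.68 for Pdgfc, and -0.67 and -0.66 for 1110032E23Rik. In 8 of the 9 genes, which were picked for their small p, all 4 mutant arrays lay on the same side of all 3 control arrays, against 5.71% of probes by chance. The exception was LOC546015, with 3 of 4 mutant arrays above the controls and mutant replicate 4 at 8.52 against 8.89 in control replicate 2. Other probes of 2 called genes had the same sign without passing, at 0.41 and 0.58 for Ank2 and 0.27 for Lyzs. The brighter probe under the lysozyme symbol Lyz, joined with Lyzs in the macrophage list, differed by 0.14 (SE 0.13, adjusted p = 0.835).

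**Figure D1:**
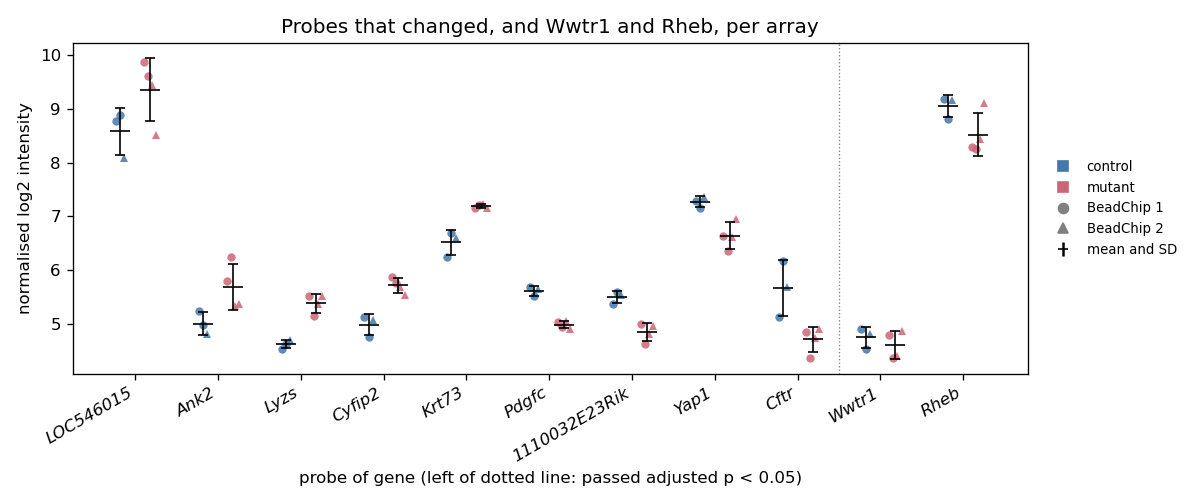
Normalised log2 intensity per array of the probes that changed (left of the dotted line) and of Wwtr1 and Rheb, with control arrays in blue, mutant arrays in red, the BeadChip as the marker shape, and bars for the mean and SD (n = 3 control and n = 4 mutant arrays). The 4 mutant arrays lie below the 3 control arrays for Yap1 (6.64 against 7.27 on average), while Wwtr1 arrays overlap and mutant replicate 4 lies among the controls for Rheb.

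The count of 9 changed with single arrays. Limma called 14 probes without control replicate 1 (5 of them among the 9), 1 without control replicate 3 (0 of the 9), 9 without mutant replicate 2 (9 higher, 0 lower, 1 of the 9) and 4 without mutant replicate 4 (3 of the 9), so that Krt73 and Pdgfc were not called with any array left out. It called 0 without control replicate 2, mutant replicate 1 or mutant replicate 3, where 1041, 1018 and 1197 probes had an unadjusted p under 0.05. With all arrays 1174 probes (8.00%) had such a p, against 733 expected of independent probes, and 2 of the 34 splits of the arrays that could be fitted gave as many, the real one included, with 1205 in the other. That other split only moved mutant replicate 3 to the side of the controls. Median scaling gave 9 higher and 0 lower probes in place of 5 and 4, with 5 shared. Of the same 34 splits, 2 called at least 9 probes, the real one included, and the other only moved mutant replicate 2 to the side of the controls.

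The genes next in rank in each direction did not pass the threshold. The smallest adjusted p among them belonged to Gadd45g, a stress-induced gene of growth arrest, at 0.63 (SE 0.12, adjusted p = 0.0552). Enam, which encodes an enamel matrix protein, differed by 0.90 (SE 0.18, adjusted p = 0.134) and Col1a1, the main collagen of bone and dentin, by 1.26 (SE 0.26, adjusted p = 0.152). On the lower side, the transcription factor gene Elf1 differed by -0.51 (adjusted p = 0.163). Values with an adjusted p of 0.295 were those of Calu, a calcium-binding protein of the secretory pathway, at -0.45, Serpinh1, the collagen chaperone, at -0.50, and Rheb, the GTPase that activates mTORC1, at -0.60 (SE 0.15). A second Rheb probe differed by -0.20 (SE 0.11), and mutant replicate 4 measured 9.10 for Rheb against 9.06 ± 0.21 (SD, n = 3) in controls. Of 3 other Calu probes, the brightest differed by 0.24 (adjusted p = 0.598), opposite in sign, and the others by -0.15 and -0.29.

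Of 34 gene lists, 31 had at least 5 tested members, and limma's camera with its preset correlation called 5 of them, 2 higher and 3 lower. Genes of p53 targets and apoptosis rose as a list (mean log2 difference 0.14, 22 of 26 members positive, adjusted p = 0.000423; adjusted p = 0.290 with an estimated correlation), and its mean lay above all controls in all 4 mutant arrays. No member passed over all probes. Adjusted over the list alone, 4 members were higher and 0 lower: Bbc3, the apoptosis inducer PUMA, at 0.52 (SE 0.11), Cdkn1a, the cell cycle inhibitor p21, at 0.52 (SE 0.11), the antiproliferative gene Btg2 at 0.46 (SE 0.11), and Dcxr at 0.33 (SE 0.11), the last named after its value was seen. Second probes differed by 0.16 (SE 0.11) for Bbc3 and 0.15 (SE 0.11) for Dcxr. Another Cdkn1a probe of similar brightness differed by 0.51 and a dim probe by 0.030. The list mean was 0.13 on the first chip and 0.14 on the second.

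Genes of G2 and mitosis fell as a list (mean log2 difference -0.16, 29 of 32 members negative, adjusted p = 3.57e-05; adjusted p = 0.818 with an estimated correlation). No member passed over all probes or adjusted over the list alone, and 7 members were lower and 0 higher at an unadjusted p under 0.05. The mitotic kinesin Kif2c differed by -0.57 (SE 0.15) and Anln, the cytokinesis scaffold anillin, by -0.36 (SE 0.12), while a second Anln probe differed by 0.15. Mki67 had no probe on the array. The list mean was -0.11 on the first chip and -0.24 on the second, with mutant replicate 4 at -0.40 and mutant replicate 3 at 0.033, and the call was lost without mutant replicate 4 (mean -0.077, adjusted p = 0.0956) or control replicate 3 (mean -0.11, adjusted p = 0.0502), whose absence leaves the difference of the first chip, where the list was called alone (adjusted p = 0.0361).

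Cholesterol and fatty acid synthesis genes fell as a list (mean log2 difference -0.13, 19 of 22 members negative, adjusted p = 0.00381; adjusted p = 0.818 with an estimated correlation). Srebf1, the transcription factor that drives lipid synthesis genes, stood at 0.40 (SE 0.13), against the direction of its list, with a second probe at -0.22, and the sterol oxidase gene Sc4mol, now Msmo1, at -0.38 (SE 0.14). Neither passed. The list mean was -0.14 on the first chip and -0.11 on the second, and the call was lost without control replicate 2 (mean -0.082, adjusted p = 0.111), without mutant replicate 2 (mean -0.055, adjusted p = 0.286) and on the second chip alone (adjusted p = 0.0522), while the mean was -0.19 without mutant replicate 1. Glycolysis and hypoxia targets also fell as a list (mean -0.12, 16 of 18 members negative, adjusted p = 0.00443; adjusted p = 0.729 with an estimated correlation), with all 4 mutant list means below the controls and means of -0.15 on the first chip and -0.072 on the second, where the call was lost (adjusted p = 0.253). The glycolytic enzyme genes Pkm2, now Pkm, and Eno1 differed by -0.31 (SE 0.11) and -0.28 (SE 0.11), and no member passed. Macrophage and leukocyte markers rose as a list (mean 0.15, 14 of 16 members positive, adjusted p = 0.0066; adjusted p = 0.818 with an estimated correlation), by 0.033 on the first chip and 0.32 on the second. Beside it, odontoblast and osteoblast markers, not called, had means of 0.052 and 0.47 on the 2 chips, and both lists were highest in mutant replicates 3 and 4 (0.25 and 0.35 for macrophage markers, 0.42 and 0.45 for the others) and lowest of the mutants in mutant replicate 2 (-0.0048 and -0.12). Aif1, a macrophage calcium-binding protein, differed by 0.27 (SE 0.14), with other probes at 0.35 (limma adjusted p = 0.470) and 0.18. The leukocyte antigen gene Cd53 differed by 0.27 (SE 0.16). At 1 probe per gene, 0 members had an unadjusted p under 0.05. The macrophage call was lost without control replicate 2 (mean 0.098, adjusted p = 0.168) or mutant replicate 4 (mean 0.11, adjusted p = 0.0956), while the mean was 0.25 without control replicate 1. It was also lost without control replicate 3 (mean 0.033, adjusted p = 0.783), whose absence leaves the difference of the first chip, and on the first chip alone (adjusted p = 0.773).

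**Figure D2:**
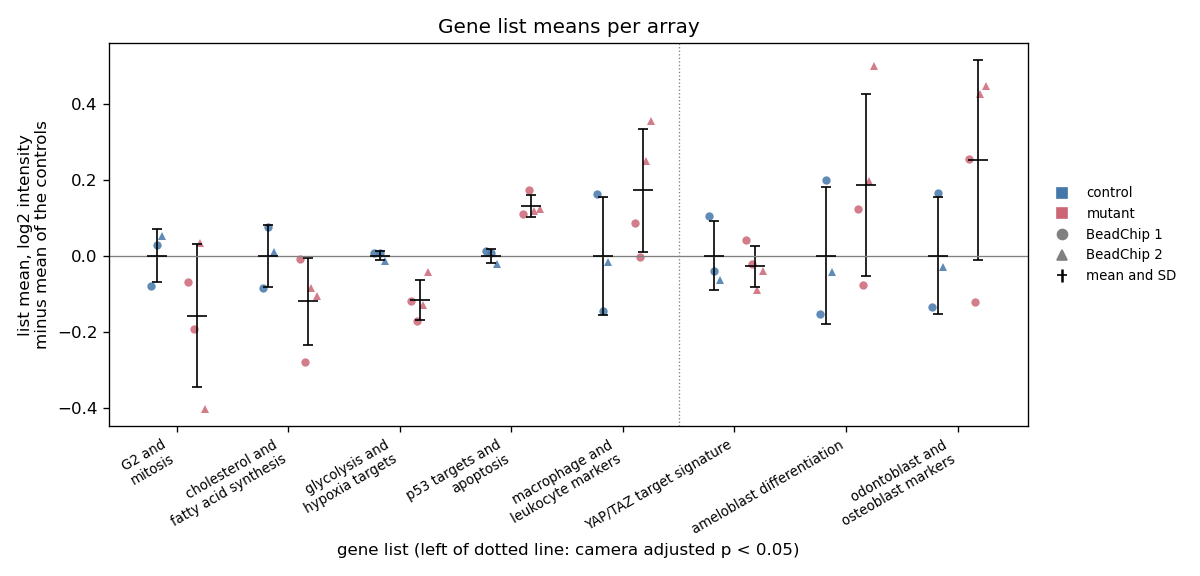
Mean log2 intensity of gene lists per array, minus the mean of the control arrays, for the 5 lists that camera called (left of the dotted line) and 3 lists that it did not call, with control arrays in blue, mutant arrays in red, the BeadChip as the marker shape, and bars for the mean and SD (n = 3 control and n = 4 mutant arrays). All 4 mutant arrays lie above the controls for p53 targets and below them for glycolysis, and the G2 and mitosis mean of mutant replicate 4 lies lowest at -0.40.

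With an estimated correlation, camera called 0 of the 31 lists, of which 2 had an unadjusted p under 0.05. The estimate was 0.59 for G2 and mitosis and -0.021 for p53 targets, below the preset 0.01. The lost p53 call therefore does not come from a correlation above the preset. Its unadjusted camera p still rose from 2.73e-05 to 0.00937. The estimated setting thus changes more than the correlation, which may hold for the other lists too. With the preset correlation camera called 3 lists without mutant replicate 4. At that setting 15 of the 34 splits of the arrays called at least 5 lists, the real one included. The fry test for movement in 1 direction also called 0, with 2 at an unadjusted p under 0.05 and the smallest adjusted p at 0.0517 for p53 targets. Its test for change in either direction called 3 lists, p53 targets and apoptosis (adjusted p = 1.82e-06), the mTOR pathway (adjusted p = 0.00272) and G1 cyclins and Cdk inhibitors (adjusted p = 0.00272).

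Lists chosen for the targeted pathway and the growth and adhesion signals around it were not called by camera. The YAP/TAZ target signature had a mean log2 difference of -0.014 and a median of 0.0068 over 13 tested members, with 7 positive and 6 negative (adjusted p = 0.872). Its member Cyr61, now Ccn1, a matricellular target of YAP, differed by -0.46 (SE 0.13), passed when adjusted over the list alone, and had 2 more probes at -0.34 and -0.22. Ctgf, now Ccn2, another matricellular target, differed by 0.032 (SE 0.15), and the nucleotidase gene Nt5e by -0.24, with a second probe at 0.072. The target genes Ankrd1, Lats2 and Amotl2 were detected on 0, 0 and 1 arrays and were not tested. Hippo pathway components had a mean of -0.053 over 16 members (adjusted p = 0.390), with the kinase gene Stk3 at 0.33, Mobkl1a, now Mob1b, at -0.33 and the YAP partner Tead1 at -0.016. The mTOR pathway had a mean of -0.029 over 37 members (adjusted p = 0.685). Of its members Rheb, at -0.60, passed when adjusted over the list alone, and Sesn1, a stress-induced inhibitor of mTORC1, differed by -0.37. Integrins and focal adhesion genes had a mean of -0.0082 over 31 members (adjusted p = 0.748). Among them were the adaptor genes Fermt1 at 0.45 and Ilk at -0.26 (second probe 0.063), the integrin gene Itga3 at 0.11 and the focal adhesion kinase gene Ptk2 at -0.12. Basement membrane and hemidesmosome genes had a mean of -0.032 over 19 members (adjusted p = 0.659). Agrn at 0.22 and the integrin gene Itga6 at -0.21 did not pass (limma adjusted p = 0.635 and 0.653).

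Ameloblast differentiation genes showed values in both directions, with a mean of 0.16 over 10 tested members (adjusted p = 0.390), 0.0016 on the first chip and 0.39 on the second. Camera called the list without control replicate 2 (mean 0.29, adjusted p = 0.0180) and on the second chip alone (adjusted p = 0.000407), while its mean was 0.0016 without control replicate 3, 0.25 without mutant replicate 2 and 0.082 without mutant replicate 4. Adjusted over the list alone, 1 member was lower, Cftr, and 3 were higher, the enamel matrix genes Ambn at 1.12 (SE 0.24), Enam at 0.90 and Amelx at 0.46 (SE 0.17). On the first and the second chip the differences were 0.57 and 1.94 for Ambn, 0.52 and 1.46 for Enam, and 0.061 and 1.06 for Amelx. Beside them, odontoblast and osteoblast markers had a mean of 0.22 over 11 members (adjusted p = 0.120), 0.052 on the first chip and 0.47 on the second, with the osteocalcin gene Bglap2 at 1.24 (SE 0.41), 0.26 on the first chip and 2.71 on the second. Camera called these markers without control replicate 2 (mean 0.33, adjusted p = 0.00195), without mutant replicate 2 (mean 0.35, adjusted p = 0.00106), without the chip term (adjusted p = 0.0222) and on the second chip alone (adjusted p = 1.98e-06), and their mean was 0.052 without control replicate 3. The sphingomyelinase gene Smpd3 was detected on 0 control and 4 mutant arrays. It measured at least 1.05-fold higher in the mutant arrays when undetected values are set to the lowest signal detected on each array (adjusted p = 0.481). Dental mesenchyme and fibroblast markers had a mean of 0.18 over 14 members (adjusted p = 0.120), 0.16 on the first chip and 0.20 on the second. They were called without control replicate 1 (mean 0.22, adjusted p = 0.00693), mutant replicate 2 (mean 0.25, adjusted p = 0.00918) or mutant replicate 3 (mean 0.21, adjusted p = 0.0398) and on the second chip alone (adjusted p = 0.0239), and their mean was 0.11 without mutant replicate 1. Adjusted over the list alone, 2 of these members were higher, Col1a1 at 1.26 and Lum at 0.50, and 1 was lower, the fibrillar collagen gene Col5a2 at -0.43. Lum, a collagen-binding proteoglycan gene, was named after its value was seen.

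Dental epithelial stem cell and progenitor markers did not move as a list (mean 0.011 and median -0.046 over 17 members, adjusted p = 0.872). Sox2, the stem cell factor of the cervical loop, differed by -0.065 (SE 0.12), Sfrp5, a secreted Wnt inhibitor of the same region, by -0.071 (SE 0.14), and Bcl11b by 0.26. P-cadherin, Cdh3, differed by -0.41 (SE 0.12) and passed when adjusted over the list alone, with 3 other probes at -0.19, -0.11 and -0.051. Basal epithelium markers had a mean of -0.028 over 16 members (adjusted p = 0.685), and the keratin gene Krt14, whose promoter drives the Cre, differed by -0.0090 (SE 0.12). Adjusted over that list alone, E-cadherin, Cdh1, was higher at 0.45 (SE 0.13) and Cdh3 lower. Cdh1 differed by 0.66 on the first chip and 0.14 on the second.

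Signalling lists were not called either. The Hedgehog pathway had a mean of -0.068 (adjusted p = 0.390), with its ligand gene Shh at -0.33 (SE 0.12) and the co-receptor gene Gas1 at -0.25. FGF and ERK feedback targets had a mean of -0.032 (adjusted p = 0.686), with Spred1 at -0.27 and Dusp6 at 0.18 (other probes -0.10 and 0.097). Wnt target genes had a mean of 0.023 (adjusted p = 0.725), with Wif1 at 0.28 and Myc at -0.24. The Notch pathway stood at -0.058 (adjusted p = 0.390), with Lfng at -0.25 and Notch2 at -0.25, and the TGF-beta and BMP pathway at -0.035 (adjusted p = 0.535), with Smad5 at -0.34 and Smad3 at -0.30.

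Of the lists on growth and death, DNA replication and S phase had a mean of -0.0032 (adjusted p = 0.879), with Clspn at -0.31 (other probes -0.30, 0.16 and -0.066) and Hells at -0.23. G1 cyclins and Cdk inhibitors had a mean of 0.027 and a median of -0.011 (adjusted p = 0.748). Adjusted over that list alone, 2 inhibitors were higher, Cdkn1a at 0.52 and Cdkn2b, the inhibitor p15, at 0.54 (SE 0.12), while cyclin D1, Ccnd1, differed by -0.0093 (SE 0.11), with other probes at 0.13 and 0.11. Inhibitors of apoptosis had a mean of -0.027 (adjusted p = 0.725), with Api5 at -0.32 and Bcl2l1 at 0.26. Cytosolic ribosomal proteins had a mean of 0.030 and a median of -0.015 (adjusted p = 0.725), with Rps27a at -0.31 and Rpl23 at 0.34, a value limited by the ceiling of 12.41 that 3 mutant arrays reached, and with other Rpl23 probes at 0.58, 0.087 and 0.031. The list was called higher without control replicate 3 (mean 0.099, adjusted p = 0.0428) and, with the same difference, on the first chip alone (adjusted p = 0.0444), against a mean of -0.072 on the second. Oxidative phosphorylation stood at 0.018 (adjusted p = 0.725), with Cox6c at 0.32 and Sdhd at 0.27, and endoplasmic reticulum stress and ATF4 targets at 0.0096 (adjusted p = 0.872), with Mthfd2 at -0.25 and Shmt2 at 0.26.

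Immediate-early and heat-shock genes, which respond to tissue handling, had a mean of 0.00071 and a median of -0.060 (adjusted p = 0.955). Adjusted over that list alone, Btg2 was higher and the chaperone gene Hspa1a lower at -0.39. The interferon response had a mean of 0.040 (adjusted p = 0.725), -0.12 on the first chip and 0.28 on the second, with Irgm1 at 0.44, and was called higher without control replicate 1 (mean 0.17, adjusted p = 0.00693) and on the second chip alone (adjusted p = 8.44e-05). Among markers of other cell types, cornifying and wound keratinocyte genes had a mean of 0.079 (adjusted p = 0.390), with Krt10 at 0.26 and Dmkn at 0.23 (other probes -0.12 and -0.011). Endothelium markers had a mean of -0.016 and a median of 0.073 (adjusted p = 0.936), with Ramp2 at -0.23 and Egfl7 at -0.10, and Schwann cell and nerve markers a mean of 0.087 (adjusted p = 0.431), with Cnp at -0.33. Erythroid and skeletal muscle markers had 4 and 3 tested members and were described only. Hbb-b1 differed by -0.15, Eraf by -0.057, Eno3 by -0.053 and Mb by 0.052, and 0 neutrophil markers were tested.

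The last comparison set these calls beside the authors' deposited table, whose values were adjusted with ComBat for the array ID. Of 17174 probes in the authors' deposited table, 13 had a q-value under 0.05, with 7 higher and 6 lower in the mutant. Of the 9 probes called here, 8 were among them, and the exception, Ank2, had a q-value of 0.0641 in the authors' deposited table. The 5 probes called only in the authors' deposited table belonged to Gadd45g (q = 0.0296), Elf1 (q = 0.0245), Serpinh1 (q = 0.0476), Bbc3 (q = 0.0168) and Ahnak2 (q = 0.0275), and all 5 had the same sign here. Ahnak2 lies outside the naming rule and was named after its values were seen. For Rheb the q-value in the authors' deposited table was 0.126. Over the 14666 probes in both, 95.9% of the differences had the same sign. The fold column of the authors' deposited table is a signed ratio of mean log2 values. Its largest size was 1.13, for Bglap2, where the deposited log2 means differed by 0.87, a 1.83-fold difference of intensities.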

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

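Among the 4 mutant arrays, 121 sets of values of named genes, gene lists and array measures were examined for a single array far from the other 3, and 8 stood apart, where chance gives about 6.05. No explanation was tested for these. Cdkn2b measured 5.66 in mutant replicate 1 against 5.47 to 5.50 in the other mutant arrays, and Sc4mol measured 5.04 in mutant replicate 2 against 5.57 to 5.66. Mthfd2 measured 4.26 in mutant replicate 4 against 4.45 to 4.48. Rpl23 measured 11.97 in mutant replicate 4 against 12.41 in each of the other 3, where its probe was the brightest of the array and quantile normalization gives the brightest probe of every array the value 12.41. The Hedgehog pathway mean, relative to the controls, was 0.013 in mutant replicate 3 against -0.095 to -0.079. In mutant replicate 1, 3 list means stood apart: the TGF-beta and BMP pathway at -0.11 against 0.00056 to 0.0076, oxidative phosphorylation at 0.11 against -0.028 to -0.017, and immediate-early and heat-shock genes at -0.065 against 0.044 to 0.064.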

How the results depend on the processing

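No alternative was chosen after the results were seen. The 9 genes that changed kept their sign in every setting in which their probe was tested, but few settings kept their calls: of 19 or 20 refits per gene, between 4 (Cftr) and 9 (Cyfip2) called it. Where a call was lost the cause was not tested, except that fits to fewer arrays have fewer degrees of freedom. Without the filter more probes were tested, and the spread was also estimated anew over all of them. The SE of Yap1 was then 0.1098 against 0.1215 at the same difference, so the number of tests was not the only change.

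Against 9 probes changed, 5 higher and 4 lower, ComBat on the chip with no chip term called 50 (33 higher, 17 lower), with all 9 among them. A fit without a chip term called 6 (3 higher). Chip 1 alone called 1 (1 higher, 0 lower) and chip 2 alone 13 (11 higher, 2 lower), with 0 of the 9 in either; on chip 2 the lone control is assumed to vary like the mutant arrays. Median scaling called 9 higher and 0 lower, with 5 of the 9 shared, and detection on all arrays left 2 lower probes of 7. Limma called 0 probes, 0 higher and 0 lower, without background correction, with the offset of 50, without the filter and in the series matrix values, where 1274, 1282, 1914 and 1536 probes had an unadjusted p under 0.05. The series matrix values, already adjusted for the array ID by the authors, were fitted with a chip term again. On the same values the authors' deposited table called 13 probes at a q-value under 0.05. Trend and robust eBayes called 8, array weights 10 and a threshold of 0.10 also 10. Leaving out 1 array at a time gave 0 to 14 probes, 0 to 9 higher and 0 to 5 lower.

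The replicate numbers were not treated as pairs in the main fit. The deviations of same-numbered arrays correlated at -0.019, 0.155 and 0.153, against -0.142 to 0.106 for other pairs of a control and a mutant array. Same-numbered arrays also share a chip, so these values cannot tell a pairing from the chip. With the replicate number as a block, 9 probes were called, 7 higher and 2 lower, 6 of them shared, and 3 gene lists.

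Yap1 was lower in every setting, past the threshold in 6 of 20. It was not past it on chip 1 alone (-0.74), chip 2 alone (-0.58), with median scaling (-0.56), without background correction (-0.45), without a chip term (-0.64), without the filter (-0.68), with the offset of 50 (-0.53) or in the series matrix values (-0.43), and ranged from -0.74 to -0.59 when 1 array was left out. Wwtr1 did not pass in any setting in which its probe was tested, which leaves out detection on all arrays. Against 5 gene lists called, an estimated correlation called 0, and leaving out 1 array called 3 to 7. The list of p53 targets was called in 22 of 23 alternatives, glycolysis in 21, G2 and mitosis in 19, cholesterol synthesis in 19 and macrophage markers in 14, with the same direction in each. Besides the arrays and chips, median scaling, no background correction and detection on all arrays ended the macrophage call. The replicate block ended the G2 and mitosis call and the macrophage call. No control shares the number of mutant replicate 4, so the block gives the differences found without that array (Yap1 -0.74 in both), and these losses are not further ones. Lists not called with all arrays gained calls in some of these settings, among them odontoblast and osteoblast, mesenchyme and ameloblast genes. Of the other values of named genes, 1314 kept their call, or did not pass either time and moved by at most 1 SE. A further 231 did not pass either time and moved by over 1 SE, 106 fell short of the threshold and 32 came to pass it. Most probes lie near the background, with a median normalised log2 value of 4.52 against a lowest value of 4.07, so offset and background correction set the size of dim differences.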

Other observations

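The comparison of splits by their balance over the chips, the use of the 95% interval for the enamel genes and the count of neighbouring pairs over all chromosomes were tests chosen after the results were seen.

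Genes outside the naming rule, chosen here after their values were seen, stood high in the ranking without passing the test. Foxo1, a transcription factor restrained by growth factor signalling, differed by -0.45 (SE 0.12, limma adjusted p = 0.313). The apoptosis-inducing flavoprotein gene Aifm1 differed by -0.48 (SE 0.12, adjusted p = 0.295), with other probes at 0.13 and -0.040. Mtap1b, a microtubule-associated protein of neurons, differed by 0.53 (SE 0.12, adjusted p = 0.163), with other probes at 0.30, 0.15 and 0.13. Esco1, a cohesin acetyltransferase gene, differed by 0.49 (SE 0.12, adjusted p = 0.280) and Tcof1, a ribosome biogenesis gene, by 0.42 (SE 0.11, adjusted p = 0.304).

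Chance could not be excluded for either count. Of 35 splits of the arrays into 3 and 4, 34 could be fitted with the chip as a term. Of these, 2 called as many probes as the real one, that one included, with 9 for the real split and 10 for the highest other. The highest other split set mutant replicates 1, 3 and 4 against the controls and mutant replicate 2, so only 1 mutant array changed sides. It is thus not free of the genotype difference. For gene lists, 15 of the 34 splits called at least the 5 lists of the real split, and the highest other called 9. The median of the other splits was 0 probes and 4 lists.

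The first pattern is that ComBat on the chip, followed by a fit without a chip term, called 50 probes where the chip term called 9. A candidate explanation is that this order of steps overstates the evidence. Over the other splits treated in the same way, the median was 4 probes, between the bounds set for and against this explanation, and 21 of the 33 other splits called at least 1 probe against 10 with the chip term. The 4 splits whose group of 3 lay wholly on the first chip called 715 to 2167 probes after ComBat and at most 3 with the chip term. These splits nearly follow the chips, so their counts cannot tell a structure of the samples from a chip difference that ComBat keeps with its covariate. The 17 other splits balanced like the real one called 0 to 38, and the 12 with 1 array of the first chip in the group of 3 called 0 to 50. Thus 6 of the 34 splits, the real one included, called at least 50. For the real split, 2530 probes had an unadjusted limma p under 0.05 after ComBat, against 1174 with the chip term. The fit after ComBat counted 5 residual degrees of freedom against 4, though the chip had already been estimated from these arrays. How much this adds to the 50 calls stays open. Yap1 differed by -0.665 (SE 0.094) after ComBat and by -0.675 (SE 0.12) with the chip term, and Wwtr1 by -0.150 (SE 0.115) and -0.153 (SE 0.140). For these 2 genes ComBat narrowed the SE and did not enlarge the difference. Whether it uncovers a difference between the genotypes in the other probes stays open.

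The second pattern is the enamel matrix genes Ambn, Enam and Amelx, grouped after their high values were seen, with a mean log2 difference of 0.83 (SE 0.36, 95% interval -0.18 to 1.83), although Amelx differed by 0.061 on the first chip and 1.06 on the second. Leaving out mutant replicate 4, the highest, gave a difference of 0.64 (SE 0.29), above the 2 SE set in advance. Those were too few for 3 residual degrees of freedom (95% interval -0.28 to 1.56). The interval of all arrays spanned both signs as well, so this fit cannot decide on a single mutant array as the source. Mutant replicates 1 and 3 also lay above the controls, at enamel means of 7.30 and 7.59, so mutant replicate 4 was not the only high array. More bone or odontoblast tissue in the mutant dissections may contribute. With the mean of 10 such markers as a covariate the difference was 0.40 (SE 0.32), which is under 0.5 times the first value and above 1 SE, so that this source and an untested effect of the genotype on enamel genes cannot be told apart with 7 arrays. Mutant replicate 2 was lowest of the mutants in both, with an enamel mean of 6.79 against 6.42 to 6.80 in controls and a marker mean of 4.84 against 4.82 to 5.08.

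The third pattern is that Pdgfc and 1110032E23Rik, both lower, are near neighbours, with 3 protein-coding genes between them in the GRCm38.p6 annotation, and that 3 of the 9 called genes, Ank2 included, lie on their chromosome. A chromosome segment that differs between the genotypes could lower both. Among 21 tested neighbours, 3 had an unadjusted p under 0.05 (14.3%, exact 95% interval 3.05% to 36.3%) against 8.23% of the other tested genes (hypergeometric p = 0.247), and all 3, Trim59, Plrg1 and Mnd1, named after their values were seen, lay at 1.06, 0.28 and 0.47, opposite in sign to the pair. Among the 100 genes of smallest p, 14 next neighbours lay within 10 tested genes of each other against a median of 9 in random draws (permutation p = 0.0814). Neither test decides, and a genotype effect on both genes stays open as well.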
